A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

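Total RNA of 12 cultures of Saccharomyces cerevisiae BY4741 was measured on 12 Affymetrix Yeast Genome 2.0 arrays, each culture on an array of its own. BY4741 is a haploid laboratory strain of mating type a without working copies of HIS3, LEU2, MET17 (also called MET15) and URA3 on its chromosomes. Per the labels, the cells carried a plasmid named p416-TEFmut2 with SPT15, which encodes the TATA-binding protein, or with the mutant form spt15-300. They are called the wild type and the mutant here. Each strain grew in minimal medium without uracil with 0% ethanol and 20 g/L glucose, or with 5% ethanol and 60 g/L glucose. Ethanol and glucose changed together, so no comparison separates them. The medium with 5% ethanol is called the ethanol medium. Per the labels' protocols, cultures grew at 30 °C in closed tubes with shaking and were harvested near an optical density of 0.4, and RNA was extracted with a commercial kit and labelled with biotin. The series' design describes 3 biological replicates in each of the 4 groups.

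The deposited table holds 1 intensity per probe set and array for 10928 probe sets, made by the authors with RMA (robust multi-array averaging, which corrects background, aligns arrays by quantiles and summarises the probes of a probe set), per the submitters' processing notes. Its version, its settings and whether all 12 arrays were processed together are not given in the sources used here. The values are on a linear scale, from 6.16 to 22228.3, so log2 was taken here before any test, with no pseudocount. The title of replicate 2 of the mutant in the ethanol medium calls that array an outlier. It was left out of the tests, which used 11 arrays, and brought back as an alternative. Arrays give no depth, and the number of arrays per group limits the precision.

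Probe sets were named with the platform's annotation, which lists 7245 of them. Of these, 5498 matched single S. cerevisiae genes of the RefSeq gene table of the R64 assembly, and 1 had several genes. The other 1746, whose gene is not in that table, were taken as Schizosaccharomyces pombe. A further 213 are control or reporter probe sets, and 3470 have no gene named here. Symbols were updated for 12 genes through the same gene table. For the 47 genes with several probe sets, the probe set with the highest mean was used, which left 5449 genes. Probe sets shared with near-identical sequences, by Affymetrix's suffix in the probe set's name, measure 118 of these genes, and such genes are named with that caveat. The array also carries S. pombe probe sets, which served as background because no S. pombe RNA was part of the design. A gene was dim in a group when no array there read it above that array's 95th percentile of S. pombe probe sets. This percentile was on average 7.24 on the log2 scale, and 139 genes were dim in all 4 groups. Where 1 of the 2 groups was dim, the fold is a bound, written "at least": the brighter mean over the mean, per array of the dim group, of the higher of that percentile and the gene's own value. No fold is given where both groups were dim or where the bound was under 1.

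Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a moderated linear model with 1 mean per group and 7 residual degrees of freedom plus 2.73 from the prior). All 4 groups shared an estimate of the spread. The 5 comparisons were mutant against wild type in each medium, the ethanol medium against the other in each strain, and the interaction, which is the mutant's medium response minus that of the wild type. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 5449 genes. Adjusted p-values of genes are limma's throughout. The 35 gene lists, with 933 entries of which 917 were measured, were written before the data were examined, as were the tests of the comparisons, the alternatives and the rule for naming genes. Some tests of the closing section were chosen later, as said there. Lists were tested with limma's camera, which asks whether a list's genes move further than other genes, at a preset correlation between genes of 0.01 and adjusted over the 35 lists of a comparison. An alternative was camera with a correlation estimated from the data, which also tests with the 7 residual degrees of freedom. Another was fry, which tests whether a list's genes move one way on balance. A count of changed list members is given over all genes and also adjusted over the list alone.

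Named genes are the 10 highest and 10 lowest log2 changes of each comparison between groups among changed genes whose arrays did not overlap between the groups, and the 5 highest and 5 lowest of the interaction. Up to 4 members with the smallest p from each list described, and SPT15, URA3, HIS3, LEU2, MET17 and PHM6, were also named. Other processing was tried 1 choice at a time: all 12 arrays with or without array weights, the replicate number as a block, array medians aligned, a repeated quantile normalization, leaving out the lowest 25% of genes, an offset of 32 before log2, the mean of a gene's probe sets, a variance trend with robust fitting, only the groups compared, an adjusted p under 0.01, and leaving out each of the 11 arrays in turn. Leaving out an array of the mutant in the ethanol medium leaves 1 there, which is then assumed to vary like the other groups. The limma steps were tested on 20 simulated data sets of 5449 genes for each of the 4 comparisons between groups. The interaction was not simulated. Each set had 50 changed genes of each size, and its noise was drawn independently for each gene and array. In the data noise is shared: same-numbered arrays correlated up to 0.709 after group means were removed. The shares below therefore need not hold for the real calls. In the comparison of mutant and wild type without ethanol the limma steps recovered 69.5% of genes changed by 0.3 on the log2 scale, 90.0% at 0.5 and 98.8% at 1. Of the calls 4.89% were false. With ethanol the shares were 61.2%, 85.9% and 98.4%, with 5.38% false. For the medium response they were 71.0%, 89.2% and 99.3% in the wild type, with 5.36% false, and 63.4%, 87.6% and 98.1% in the mutant, with 4.52% false. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.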

Results

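Transcript levels were measured in yeast that carried an extra copy of SPT15, the gene of the TATA-binding protein, in its wild type or its mutant spt15-300 form. Each strain grew with 0% ethanol and 20 g/L glucose or with 5% ethanol and 60 g/L glucose, in 3 cultures per group. The 11 arrays used here correlated with each other at 0.943 to 0.999 over the yeast genes, and at 0.993 or more within a group. Their median log2 intensity over the yeast genes lay between 10.46 and 10.53. The median log2 difference between 3' and 5' probe sets of 8 control genes, a sign of RNA quality, differed between groups. It was 0.240 to 0.266 in the mutant without ethanol, against 0.310 to 0.359 in the wild type there, 0.361 to 0.435 in the wild type with ethanol and 0.379 to 0.400 in the mutant with ethanol. RNA quality was not separated from the strain effect without ethanol, the medium responses or the interaction. The array whose title calls it an outlier, replicate 2 of the mutant in the ethanol medium, correlated with the others at 0.747 to 0.789. It had a median of 9.89 and was left out, so the mutant in the ethanol medium rests on 2 arrays.

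**Figure D1:**
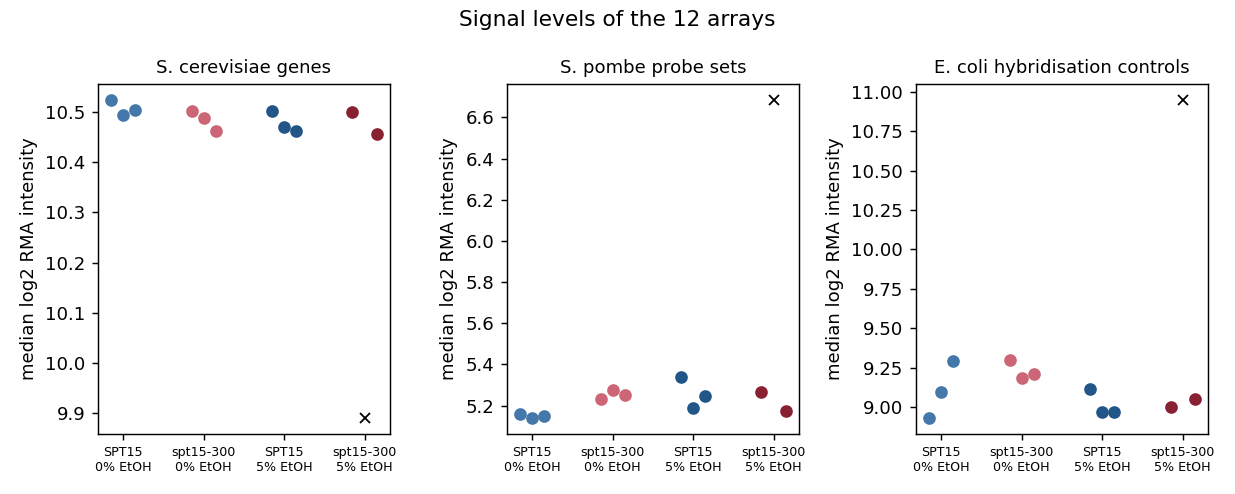
Median log2 intensity of the yeast genes and of the S. pombe probe sets on each of the 12 arrays, by group, with a cross for the array labelled an outlier. That array has a yeast median of 9.89 and an S. pombe median of 6.69, against 10.46 to 10.53 and 5.14 to 5.34 on the other 11.

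SPT15 was not called between the strains. Its log2 intensity was 13.47 ± 0.026 (SD, n = 3) in the wild type and 13.46 ± 0.020 (n = 3) in the mutant without ethanol, a difference of -0.02 (adjusted p = 0.801). In the ethanol medium it was 13.34 ± 0.021 (n = 3) and 13.30 ± 0.020 (n = 2), a difference of -0.05 (adjusted p = 0.376). These values lie near the level of the brightest 1% of genes, 13.68 in the wild type with ethanol, where a difference may not show. The probe set also reads the chromosomal gene and cannot be assumed to tell the mutant form from the wild type form, so it checks neither the plasmid nor which form a culture carried. URA3, the plasmid's marker, read 13.43 in the wild type and 13.53 in the mutant without ethanol (adjusted p = 0.0646). It was called with array weights (adjusted p = 0.00164), array medians aligned (0.0441), without the lowest 25% of genes (0.0484) and with a variance trend and robust fitting (0.00931). In the ethanol medium it was higher in the mutant by 0.19 on the log2 scale (adjusted p = 0.0130). That call ended without replicate 1 or 3 of the mutant in the ethanol medium (adjusted p = 0.0516 and 0.0617) and with only the groups compared (0.209). MET17, of which BY4741 has no working copy, lay between 7.68 and 7.90 in all 4 groups. In the fit of the 11 arrays it changed in no comparison. By the S. pombe percentile it was dim in no group. Neither was LEU2, at 7.99 in the wild type and 8.07 in the mutant without ethanol. A reading above that percentile thus does not by itself show a transcript of a working gene. PHM6 (7.59) and GIT1 (7.64) in the wild type without ethanol read about as low, as did HXT2 (7.99) with ethanol. Their changes are therefore less certain. HIS3, of which BY4741 has no working copy either, lay between 11.31 and 11.81, far above background. What its probe set measures in these cells was not tested.

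The first comparison asked what the mutant protein changed in cells grown without ethanol. The 3 genes that rose most, PHO5, PHO84 and PHM6, belong to the list of the phosphate regulon. PHO5, a secreted acid phosphatase, was 5.64-fold higher in the mutant, from 9.18 ± 0.11 to 11.67 ± 0.037 on the log2 scale (SD, n = 3 each). PHO84, the high-affinity phosphate transporter, rose 4.54-fold from 11.08 ± 0.16 to 13.26 ± 0.041. Some genes of the general stress response and of osmotic and oxidative defence rose with them, and some of mating and pheromone response fell. In all, 890 of 5449 genes changed, 450 higher and 440 lower. The changes were small, with a median size of 0.23 on the log2 scale, and 16 genes rose at least 2-fold while 0 fell that far. Of the 35 gene lists 14 were called, 11 upward and 3 downward, and 1 of them with an estimated correlation.

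In the phosphate regulon, the targets of the regulator Pho4, 13 of 17 measured genes rose (13 adjusted over the list alone) and 0 fell, with a median of 0.57 on the log2 scale. The list's adjusted p was 5.43e-20 with camera and adjusted p = 0.0110 with an estimated correlation. Besides PHO5 (log2 change 2.49, SE 0.083, adjusted p = 1.69e-07) and PHO84 (2.18, SE 0.070, adjusted p = 1.69e-07), its members PHM6, PHM8, PHO11 and VTC3 rose. PHM6 rose by 1.85 and PHM8, a lysophosphatidic acid phosphatase, by 1.72. PHO11, an acid phosphatase on a probe set shared with near-identical sequence, rose by 1.41, and VTC3, a subunit of the vacuolar polyphosphate polymerase, by 1.14. Their adjusted p-values lay between 1.56e-06 and 5.16e-05, and each mutant array lay above each wild type array.

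**Figure D2:**
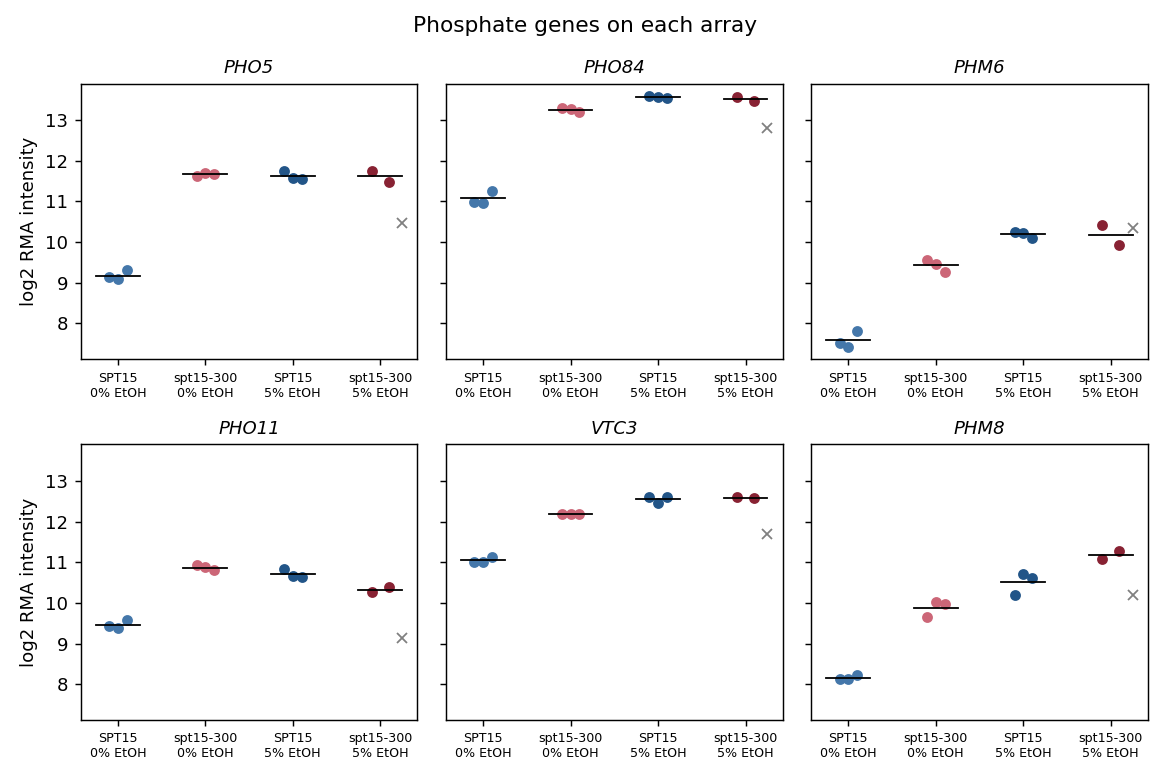
Log2 intensity of phosphate regulon genes on each array, by group, with bars for the group means and a grey cross for the array left out. PHO5 lies at 9.18 on average in the wild type without ethanol and at 11.62 to 11.67 in the 3 other groups.

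Of 30 measured genes of the general stress response driven by Msn2 and Msn4, 20 rose (21 adjusted over the list alone) and 0 fell, with a median of 0.58. Its camera adjusted p was 1.09e-16, with adjusted p = 0.375 with an estimated correlation. TKL2, a transketolase, rose 3.44-fold, FMP16, a mitochondrial protein, 3.32-fold, NQM1, a transaldolase, 2.99-fold, and ALD3, an aldehyde dehydrogenase, 2.70-fold. In the list of osmotic response and glycerol metabolism 10 of 18 genes rose (10 adjusted over the list alone, median 0.28, adjusted p = 0.179 with an estimated correlation). SIP18, a protein of desiccation tolerance, rose 2.94-fold and GPP2, a glycerol phosphatase, 1.58-fold. Oxidative defence had 12 genes higher and 1 lower of 25 (12 and 1 adjusted over the list alone, adjusted p = 0.210 with an estimated correlation). Its mitochondrial members SOD2, a superoxide dismutase, and PRX1, a peroxiredoxin, rose by 0.52 and 0.64 on the log2 scale.

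Smaller shifts upward were called for respiratory chain and ATP synthase genes (8 of 32 rose, 8 adjusted over the list alone, among them CYC1 by 0.31; adjusted p = 0.333 with an estimated correlation) and for trehalose and glycogen metabolism (5 of 18 rose, 8 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation). Heat shock proteins had 6 of 25 higher (7 adjusted over the list alone), among them HSP26 by 0.90, with adjusted p = 0.633 with an estimated correlation. Of G1/S genes 7 of 21 rose (8 adjusted over the list alone), and of G2/M and M/G1 genes 6 rose and 1 fell of 21 (6 and 1 adjusted over the list alone). These had adjusted p = 0.333 and adjusted p = 0.263 with an estimated correlation. CLB6, an S-phase cyclin, rose by 0.29 and SIC1, an inhibitor of cyclin-dependent kinase, by 0.39. Thiamine synthesis (5 of 14 higher, 5 adjusted over the list alone) and the cell wall list (3 higher and 1 lower of 26, likewise adjusted over the list alone) were called too. They had adjusted p = 0.549 and adjusted p = 0.633 with an estimated correlation. Thiamine synthesis was not called without replicate 3 of the wild type or replicate 1 of the mutant without ethanol (adjusted p = 0.145 and 0.0603), nor without the lowest 25% of genes (0.0545). The cell wall list was not called without replicate 3 of either (adjusted p = 0.140 and 0.0529).

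Among genes of a-cell mating and pheromone response, 13 of 25 fell (14 adjusted over the list alone) and 0 rose, with a median of -0.22. Its camera adjusted p was 3.23e-06, with adjusted p = 0.263 with an estimated correlation. FUS1, a membrane protein of cell fusion, fell by 0.83 on the log2 scale, BAR1, the protease that degrades alpha factor, by 0.65, PRM5, a pheromone-regulated membrane protein, by 0.63 and AGA1, the anchor of a-agglutinin, by 0.57. INO1, the enzyme of inositol synthesis, fell by 0.79, ENB1, a siderophore transporter, by 0.70 and YBL005W-A, a Ty1 Gag protein on a shared probe set, by 0.89. YCL021W-A, an uncharacterised gene, fell by 0.75. CRR1, a cell wall enzyme of spores, was lower and dim in the mutant, and no bound can be given. FIT2, a cell wall protein of siderophore retention, fell by 0.65 (adjusted p = 0.0311), a call that ended without replicate 1 or 2 of the wild type (adjusted p = 0.111 and 0.104) and with only the groups compared (adjusted p = 0.0511). Of 18 genes of the vacuolar ATPase, 5 fell (5 adjusted over the list alone), with adjusted p = 0.179 with an estimated correlation. Of 34 proteasome genes 3 fell and 1 rose (0 adjusted over the list alone), with adjusted p = 0.633 with an estimated correlation. The proteasome list was not called with array medians aligned (adjusted p = 0.106) or without replicate 3 of the wild type or replicate 1 of the mutant (0.0810 and 0.0583).

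The count of 890 genes rests on 3 arrays per group. It was 464 or 478 without replicate 1 or 2 of the wild type and 454 or 472 without replicate 2 or 3 of the mutant, and 13 with the array labelled an outlier brought back. With array medians aligned, 491 genes were higher and 274 lower, a share of 64.2% higher against 50.6%. With all 12 arrays and array weights, 2726 genes changed, 1179 higher and 1547 lower, a share of 43.3%. In that fit replicate 2 of the mutant and of the wild type without ethanol weighed most, 10.6 and 6.38.

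The second comparison asked what the mutant changed in the ethanol medium. The phosphate genes did not stand apart there: 2 of 17 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.135), and PHM6 differed by -0.02 (adjusted p = 0.926). HUG1, an inhibitor of ribonucleotide reductase induced by DNA damage, rose 2.22-fold from 9.02 ± 0.10 (SD, n = 3) to 10.17 ± 0.056 (n = 2). HXT5, a hexose transporter of slow growth, rose 2.19-fold, and the defence enzymes SRX1 (sulfiredoxin) and GTT2 (glutathione transferase) rose 1.78-fold and 1.73-fold. With only the groups compared, 6 of the 20 genes named for their size of change kept their calls, HUG1, SRX1, GTT2, PRM5, INO1 and BAR1, and HXT5 did not (adjusted p = 0.109). Of the respiratory chain list 16 of 32 genes fell and 1 rose, and of the pheromone list 9 of 25 fell. The calls of these lists were lost with adjusted p = 0.546 and adjusted p = 0.633 with an estimated correlation. In all, 638 genes changed, 312 higher and 326 lower, with a median size of 0.26 on the log2 scale, and 4 rose and 1 fell at least 2-fold. Of the 35 gene lists 12 were called, 9 upward and 3 downward, and 0 with an estimated correlation. Without the lowest 25% of genes 8 were called, 5 upward, and the heat shock, cell wall, nitrogen and thiamine lists were not (adjusted p = 0.0566, 0.0527, 0.0691 and 0.0657).

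Of 32 measured genes of the respiratory chain and ATP synthase, 16 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.14. Its camera adjusted p was 2.13e-07, with adjusted p = 0.546 with an estimated correlation. RIP1, the iron-sulfur subunit of complex III, fell by 0.29 on the log2 scale (SE 0.046, adjusted p = 0.00814, and 0.168 with only the groups compared). COX4, a subunit of cytochrome oxidase, fell by 0.22, a call that ended without replicate 3 of the mutant in the ethanol medium (adjusted p = 0.0656) and with only the groups compared (0.192). Of 25 mating and pheromone genes 9 fell (13 adjusted over the list alone) and 0 rose, with adjusted p = 0.633 with an estimated correlation. PRM5 fell by 0.88, BAR1 by 0.61, FUS1 by 0.57 and STE2, the alpha factor receptor, by 0.40. With only the groups compared, FUS1 and STE2 lost their calls (adjusted p = 0.0567 and 0.134). Of 128 ribosomal protein genes 3 fell (0 adjusted over the list alone), with a median of -0.05, a camera adjusted p of 0.000411 and adjusted p = 0.776 with an estimated correlation.

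Oxidative defence had 9 genes higher and 1 lower of 25 (11 and 1 adjusted over the list alone), with adjusted p = 0.546 with an estimated correlation. Besides GTT2, they included GPX2, a glutathione peroxidase (0.41 on the log2 scale), and ATR1, a multidrug efflux pump (0.35). Nitrogen catabolite repressed genes had 7 of 22 higher (8 higher and 1 lower adjusted over the list alone), with adjusted p = 0.757 with an estimated correlation. MEP3, an ammonium permease, rose by 0.38 and DUR3, a urea transporter, by 0.44. With only the groups compared, GPX2, ATR1, MEP3 and DUR3 lost their calls (adjusted p = 0.122, 0.135, 0.120 and 0.134). The general stress list had 6 of 30 higher (7 adjusted over the list alone) and adjusted p = 0.776 with an estimated correlation, and it was not called without replicate 3 of the mutant in the ethanol medium (adjusted p = 0.0717). Osmotic response (3 of 18 higher, 3 adjusted over the list alone), pleiotropic drug resistance (4 of 17, 5 adjusted over the list alone) and thiamine synthesis (3 of 14, 3 adjusted over the list alone) were called upward. Each had adjusted p = 0.633 with an estimated correlation. The iron regulon had 2 higher and 1 lower of 22 (3 and 1 adjusted over the list alone), with adjusted p = 0.757 with an estimated correlation. The cell wall list (5 of 26 higher, 5 adjusted over the list alone) and heat shock proteins (1 of 25 higher, 0 adjusted over the list alone) had adjusted p = 0.764 and adjusted p = 0.776 with an estimated correlation. Without replicate 1 of the wild type or replicate 3 of the mutant in the ethanol medium, neither was called (cell wall adjusted p = 0.0645 and 0.137, heat shock adjusted p = 0.656 and 0.812). Heat shock was also not called without replicate 3 of the wild type without ethanol (adjusted p = 0.0556).

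Most of the other named genes depended on single arrays, and of the others only INO1 kept its call with only the groups compared. TKL2 rose 2.02-fold, SGA1, a glucoamylase of sporulation, 1.95-fold, and SPS100, a spore wall protein, 1.86-fold, and YCL021W-A fell by 0.65 on the log2 scale. These calls ended without replicate 3 of the mutant in the ethanol medium (adjusted p = 0.0988, 0.0647, 0.0696 and 0.0612). OYE3, an NADPH oxidoreductase, rose 2.04-fold and GRE1, a hydrophilin, 1.79-fold, with calls that ended without that array (adjusted p = 0.160 and 0.0996). OYE3 also lost its call without replicate 2 of the wild type (0.0520) and GRE1 without replicate 1 of the mutant (0.0505). INO1 fell by 0.68 and PES4, an RNA-binding protein of meiosis, by 0.68, and each lost its call without any of replicates 1 and 2 of the wild type and 1 and 3 of the mutant in the ethanol medium. Their adjusted p-values were then 0.0505, 0.0670, 0.0697 and 0.130 for INO1 and 0.0620, 0.0948, 0.102 and 0.119 for PES4. SPS22, a spore wall gene dim in the mutant, was at least 1.32-fold lower, and YBL005W-A fell by 0.73. Each lost its call without replicate 1 or 2 of the wild type or 3 of the mutant in the ethanol medium (adjusted p = 0.0505, 0.110 and 0.147 for SPS22, and 0.0646, 0.123 and 0.272 for YBL005W-A). Replicate 1 of the wild type and 2 of the mutant without ethanol did the same (0.0576 and 0.0539, and 0.0607 and 0.0515). SPS22 also lost it without replicate 1 of the mutant with ethanol (0.104), and YBL005W-A without replicate 2 of the wild type or 3 of the mutant without ethanol (0.0633 and 0.0611). YGL262W was higher, and YGL138C, IMD2 and YER175W-A were lower, but all 4 were dim in both strains. YER175W-A lost its call in 8 of the 11 fits that left out 1 array, with adjusted p = 0.162 without replicate 3 of the mutant in the ethanol medium.

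The count of 638 depends on the arrays used. It was 72 and 296 without replicate 3 or 1 of the mutant in the ethanol medium, and 360, 184 and 1326 without replicate 1, 2 or 3 of the wild type there. It was 398 and 348 without replicate 1 or 2 of the wild type without ethanol, 336 and 396 without replicate 2 or 3 of the mutant without ethanol, 6 with only the groups compared, and 0 with all 12 arrays.

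**Figure D3:**
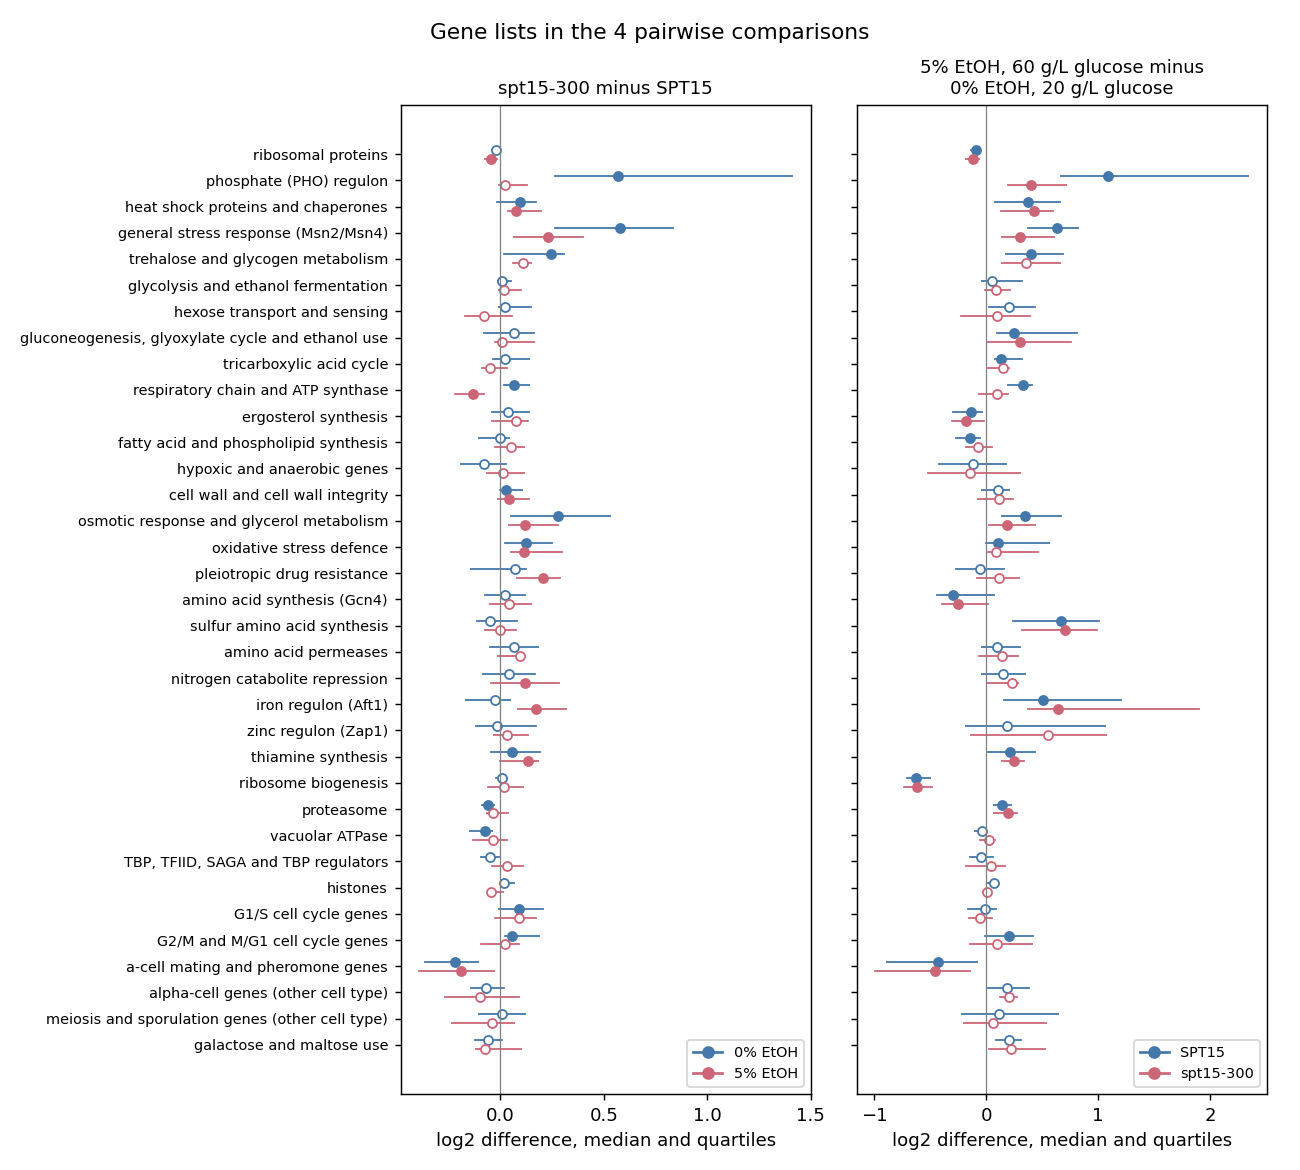
Median log2 change of each gene list with its quartiles in each comparison, with filled points where camera's adjusted p was under 0.05. The phosphate regulon has a median of 0.57 in the mutant without ethanol and 0.02 with ethanol.

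The strain effects of both media went together across genes, with a Pearson correlation of 0.44 and a Spearman correlation of 0.351. Genes are not independent replicates. These 2 comparisons share no array, but they share each gene's estimate of the spread. Their calls are therefore not independent, which the counts for independent lists leave out. Both media had 154 genes higher in the mutant, where independent lists would share 25.8, and 101 lower, where they would share 26.3. Opposite directions were called for 5 and 5 genes.

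The response of the wild type to the ethanol medium was far larger. HSP30, a stress protein of the plasma membrane, rose 12.5-fold, from 8.32 ± 0.066 to 11.97 ± 0.30 on the log2 scale (SD, n = 3 each). GIT1, a glycerophosphoinositol transporter, rose 9.38-fold, from 7.64, about the level of MET17. HXT2, a high-affinity glucose transporter repressed at high glucose, was 12.7-fold lower, at 7.99 ± 0.11 against 11.66 ± 0.0044. Many phosphate, sulfur, iron and stress genes rose, while many of ribosome biogenesis and amino acid synthesis fell. In all, 3312 of 5449 genes changed, 1730 higher and 1582 lower, with 168 higher and 46 lower at least 2-fold. Of the 35 gene lists 20 were called, 14 upward and 6 downward, and 0 with an estimated correlation.

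Phosphate genes rose here as well, 16 of 17 (16 adjusted over the list alone), with a median of 1.09 and adjusted p = 0.104 with an estimated correlation. PHM6 rose 6.08-fold, PHO84 5.62-fold and PHO5 5.44-fold. Sulfur amino acid synthesis had 24 higher and 1 lower of 27 (likewise adjusted over the list alone), with a median of 0.67 and adjusted p = 0.399 with an estimated correlation. MET2, homoserine acetyltransferase, rose 4.16-fold and MET3, ATP sulfurylase, 3.25-fold. The iron regulon had 16 higher and 2 lower of 22 (16 and 2 adjusted over the list alone), with adjusted p = 0.455 with an estimated correlation, among them the siderophore transporter ARN1 (3.96-fold) and FIT2 (5.03-fold). In the general stress list 27 rose and 1 fell of 30 (27 and 1 adjusted over the list alone), and among heat shock proteins 17 rose and 1 fell of 25 (18 and 1 adjusted over the list alone). Each had adjusted p = 0.495 with an estimated correlation. HSP26 rose 3.86-fold and SSA4, an inducible Hsp70, 3.67-fold. Respiratory chain genes rose in 27 of 32 and fell in 2 (28 and 2 adjusted over the list alone), with a median of 0.33 and adjusted p = 0.399 with an estimated correlation, among them QCR2 of complex III by 0.54.

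Ribosome biogenesis genes fell in 69 of 71 (69 adjusted over the list alone) and rose in 0, with a median of -0.63, a camera adjusted p of 4.70e-15 and adjusted p = 0.455 with an estimated correlation. UTP13 and NOP56, proteins of the small subunit processome and the box C/D complex, fell by 0.64 and 0.59. Ribosomal protein genes fell in 66 of 128 and rose in 1 (63 and 1 adjusted over the list alone), by a median of -0.09, with adjusted p = 0.455 with an estimated correlation. Amino acid synthesis under Gcn4 had 26 lower and 7 higher of 43 (26 and 7 adjusted over the list alone) and adjusted p = 0.512 with an estimated correlation. SER3, the first enzyme of serine synthesis, fell by 1.90 while its paralog SER33 rose by 1.04, and LEU1 fell by 1.63. Mating and pheromone genes had 17 lower and 3 higher of 25 (17 and 3 adjusted over the list alone), with adjusted p = 0.399 with an estimated correlation. AGA1 fell by 1.77 and SST2, which dampens pheromone signalling, by 1.52. Ergosterol synthesis had 13 lower and 5 higher of 24 (14 and 5 adjusted over the list alone), and fatty acid and phospholipid synthesis 12 lower and 2 higher of 22 (14 and 2 adjusted over the list alone). Each had adjusted p = 0.495 with an estimated correlation. ERG7, lanosterol synthase, fell by 0.49 and ACC1, acetyl-CoA carboxylase, by 0.35.

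Other lists called upward in the wild type were the proteasome (22 of 34 higher, 22 adjusted over the list alone), osmotic response (12 of 18, 12 adjusted over the list alone), G2/M and M/G1 genes (11 higher and 1 lower of 21, likewise adjusted over the list alone) and oxidative defence (12 higher and 5 lower of 25, likewise adjusted over the list alone). All of these had adjusted p = 0.455 with an estimated correlation. GTT2 rose 4.40-fold and GRE2, a methylglyoxal reductase, 2.33-fold. The tricarboxylic acid cycle had 12 higher and 2 lower of 19 (12 and 2 adjusted over the list alone), with adjusted p = 0.495 with an estimated correlation. Trehalose and glycogen metabolism had 11 higher and 2 lower of 18 (11 and 2 adjusted over the list alone), with adjusted p = 0.576 with an estimated correlation. Gluconeogenesis and ethanol use had 12 higher and 3 lower of 21 (13 and 3 adjusted over the list alone), with adjusted p = 0.399 with an estimated correlation. It was not called once the lowest 25% of genes were left out (adjusted p = 0.926) or with a repeated quantile normalization (0.0929). Thiamine synthesis had 8 higher and 1 lower of 14 (8 and 1 adjusted over the list alone), with adjusted p = 0.455 with an estimated correlation. It was not called without replicate 3 of the wild type in either medium (adjusted p = 0.0718 and 0.0643), nor without the lowest 25% of genes (0.374).

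The other genes with the largest shifts in the wild type were YNL277W-A (at least 6.16-fold higher), OYE3 (at least 5.25-fold), HBN1, a nitroreductase-like protein (5.60-fold), and ANS1 (at least 1.67-fold). IMD2, an IMP dehydrogenase on a shared probe set, was at least 9.45-fold lower and HFM1, a helicase of meiosis, at least 2.50-fold. YNL040W fell by 2.02 on the log2 scale, UTR2, a cell wall transglycosylase, by 1.49 and ATO3, an ammonium exporter, by 1.49. SAE3 of meiosis was higher but dim in both media. Of the plasmid and marker genes, SPT15 fell by 0.13, URA3 by 0.27 and HIS3 by 0.32, and LEU2 rose by 1.66 (SE 0.20, adjusted p = 8.58e-05). The count of changed genes stayed between 2932 and 3339 when 1 array was left out and was 408 with all 12 arrays.

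In the mutant, all 14 gene lists called with the ethanol medium were among the 20 called in the wild type, in the same directions. OYE3 was at least 10.8-fold higher, HSP30 rose 13.0-fold from 8.77 ± 0.38 (SD, n = 3) to 12.48 ± 0.15 (n = 2), GIT1 11.5-fold and FIT2 8.01-fold. HXT2 was 17.4-fold lower. Many sulfur, iron, heat shock and proteasome genes rose, and many of ribosome biogenesis and amino acid synthesis fell. In all, 3404 genes changed, 1841 higher and 1563 lower, with 124 higher and 48 lower at least 2-fold. Of the 14 lists 9 were called upward and 5 downward, and 0 with an estimated correlation.

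Sulfur amino acid synthesis had 25 higher and 1 lower of 27 (25 and 1 adjusted over the list alone), with MET2 up 5.04-fold. The iron regulon had 17 of 22 higher (18 adjusted over the list alone), with ARN1 up 4.97-fold. The proteasome had 23 higher and 1 lower of 34 (23 and 1 adjusted over the list alone), with PUP1, a core subunit, up by 0.44 on the log2 scale. Each of these 3 lists had adjusted p = 0.626 with an estimated correlation. Heat shock proteins had 18 higher and 1 lower of 25 (20 and 1 adjusted over the list alone), with adjusted p = 0.694 with an estimated correlation, and HSP26 rose 2.14-fold. The phosphate list had 14 higher and 1 lower of 17 (14 and 1 adjusted over the list alone), with a median of 0.40 and adjusted p = 0.626 with an estimated correlation. PHO8, the vacuolar alkaline phosphatase, rose by 0.87 and PHM6 by 0.73. Gluconeogenesis and ethanol use (11 higher and 1 lower of 21, likewise adjusted over the list alone), thiamine synthesis (10 higher and 1 lower of 14, likewise adjusted over the list alone) and osmotic response (9 of 18 higher, 8 adjusted over the list alone) were called upward. Each had adjusted p = 0.626 with an estimated correlation. The gluconeogenesis list was not called with the lowest 25% of genes left out (adjusted p = 0.940), and neither was thiamine synthesis (0.314). The osmotic list was not called without replicate 1 of the mutant without ethanol or replicate 3 of it with ethanol (adjusted p = 0.0628 and 0.0971). The general stress list had 16 higher and 1 lower of 30 (16 and 1 adjusted over the list alone), with adjusted p = 0.745 with an estimated correlation, and was not called without replicate 3 of the mutant in the ethanol medium (0.119).

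Ribosome biogenesis genes fell in 67 of 71 (69 adjusted over the list alone) with a median of -0.62, ribosomal protein genes in 74 of 128 with 1 higher (73 and 1 adjusted over the list alone), and ergosterol synthesis genes in 14 of 24 with 2 higher (14 and 2 adjusted over the list alone). Mating and pheromone genes fell in 17 of 25 and rose in 3 (17 and 3 adjusted over the list alone). Each of these 4 lists had adjusted p = 0.626 with an estimated correlation. Amino acid synthesis under Gcn4 had 25 lower and 6 higher of 43 (25 and 6 adjusted over the list alone) and adjusted p = 0.694 with an estimated correlation. SSF1, a ribosome assembly factor, fell by 1.01, STE2 by 1.07, LEU1 by 1.65, SER3 by 1.56 and SST2 by 1.53. Respiratory chain genes were not called in the mutant, with 12 higher and 4 lower of 32 (12 and 4 adjusted over the list alone; camera adjusted p = 0.266). The other 5 lists called in the wild type alone were trehalose and glycogen metabolism and oxidative defence (adjusted p = 0.0681 each in the mutant), the tricarboxylic acid cycle (0.156), fatty acid synthesis (0.207) and G2/M and M/G1 genes (0.257). A call in 1 strain alone is not a difference between the strains. The first 3 of these were not called in the interaction (camera adjusted p = 0.157, 0.862 and 0.0694). Fatty acid synthesis and G2/M and M/G1 genes were (0.0409 and 0.0312). GTT2 rose 7.11-fold, BNA2, the first enzyme of NAD synthesis from tryptophan, 5.37-fold, and HBN1 5.05-fold, and YNL277W-A was at least 7.26-fold and LSO1 at least 1.31-fold higher. IMD2 was at least 6.68-fold lower, COS12 at least 2.22-fold, HFM1 at least 2.12-fold and BSC1 at least 1.69-fold. YNL040W fell by 1.68 and GLT1, glutamate synthase, was 2.84-fold lower. YOL131W was higher but dim in both media. SPT15 fell by 0.16, URA3 by 0.18 and HIS3 by 0.50, and LEU2 rose by 2.14 (SE 0.23, adjusted p = 4.36e-05). The count of changed genes stayed between 2535 and 3485 when 1 array was left out and was 744 with all 12 arrays.

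Across genes the medium responses of the 2 strains had a Pearson correlation of 0.905 and a Spearman correlation of 0.873, with no array in common. Both strains had 1411 genes higher, against 584 for independent lists, and 1227 lower, against 454. The shared estimate of each gene's spread is left out of these counts for independent lists as well. Opposite directions were called for 12 and 7 genes.

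**Figure D4:**
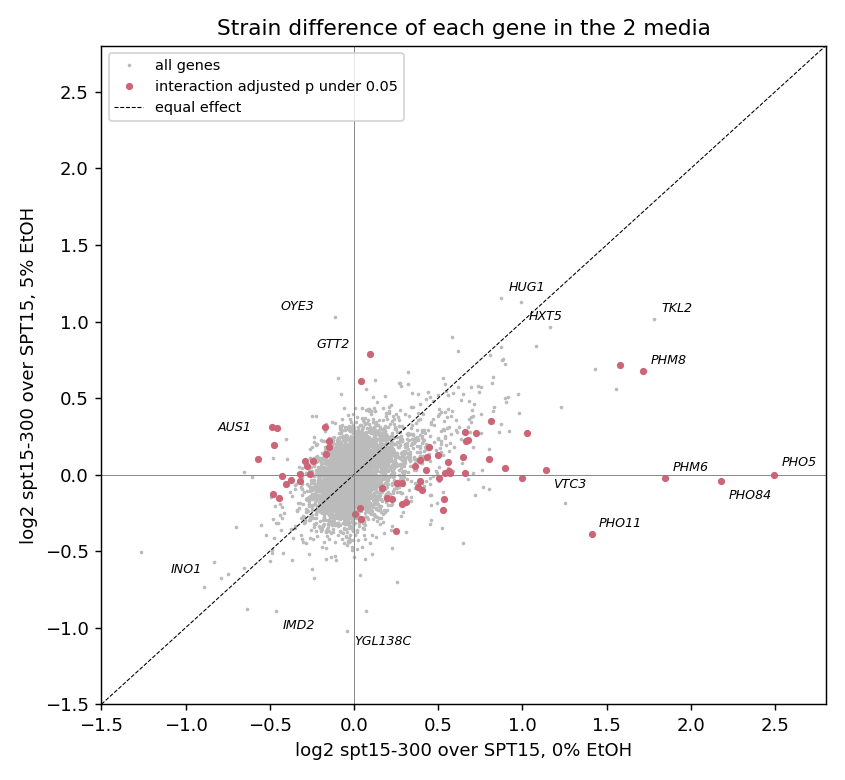
Log2 change of each gene in the mutant against the wild type with ethanol (vertical) and without (horizontal), with the 66 interaction genes in red and a dashed line of equal effects. PHO5, PHO84 and PHM6 lie far to the right, near 0 on the vertical axis.

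The interaction asked which genes responded to the ethanol medium differently in the 2 strains. The phosphate genes stood out. As a list they rose less in the mutant, with a median response of 0.40 there against 1.09 in the wild type. In the mutant, part of the wild type's rise was already present without ethanol. The list's median was 0.57 for the strain effect without ethanol against 1.09 for the medium response of the wild type. PHO5 read 9.18 in the wild type and 11.67 in the mutant without ethanol, and 11.62 in both with ethanol, an interaction of -2.50 on the log2 scale (SE 0.12, adjusted p = 8.16e-06). PHO84 had -2.22, PHM6 -1.87, PHO11 -1.80 and VTC3 -1.11. Not all of these rose in the mutant: PHO5 did not, and PHO11 fell. The mutant arrays read PHO11 at 10.805 to 10.922 without ethanol and at 10.26 and 10.388 with it. With ethanol PHO84 read 13.57 in the wild type, near the brightest 1% of genes, where the array may not show a further rise, so its value is less certain. Of 17 phosphate genes 11 had a lower response in the mutant (12 lower and 1 higher adjusted over the list alone), with a median of -0.54, a camera adjusted p of 4.24e-16 and adjusted p = 0.0226 with an estimated correlation. In all 66 genes differed, 21 with a higher and 45 with a lower response in the mutant.

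Respiratory chain genes also responded less in the mutant, by a median of -0.26, with a camera adjusted p of 4.16e-17 and adjusted p = 0.0819 with an estimated correlation. Of 32, 5 passed over all genes and 24 adjusted over the list alone, all lower. CYC1, cytochrome c, had -0.49 (SE 0.057, adjusted p = 0.00292). The general stress list had 2 of 30 lower (3 adjusted over the list alone, median -0.28), with adjusted p = 0.802 with an estimated correlation. Its member MCR1, a mitochondrial cytochrome b5 reductase, had -0.52. GTT2 (0.69), YCR102C (0.67) and YLR460C (0.76) responded more in the mutant. AUS1, a sterol transporter of anaerobic cells, had 0.80 and AGA1 0.67. Their calls ended without replicate 1 or 2 of the wild type without ethanol (adjusted p = 0.0988 and 0.0979 for AUS1, 0.120 and 0.0980 for AGA1), and also without replicate 2 or 3 of the mutant without ethanol (0.109 and 0.0923, and 0.116 and 0.103). They ended too without replicate 1 or 3 of the mutant with ethanol (0.0748 and 0.125, and 0.0837 and 0.128), and for AGA1 without replicate 3 of the wild type without ethanol (0.0744).

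The iron regulon was called upward with a median of 0.23 (0 of 22 genes over all genes, 2 higher adjusted over the list alone) and osmotic response downward with a median of -0.23 (1 of 18 lower, 3 adjusted over the list alone). G2/M and M/G1 genes had a median of -0.10 (0 of 21, 3 lower adjusted over the list alone) and pleiotropic drug resistance 0.16 (0 of 17, 0 adjusted over the list alone). Each of these 4 had adjusted p = 0.802 with an estimated correlation. Fatty acid and phospholipid synthesis had a median of 0.07 (0 of 22, 0 adjusted over the list alone) and adjusted p = 0.915 with an estimated correlation. Without replicate 3 of the wild type or 1 of the mutant with ethanol, osmotic response (adjusted p = 0.0923 and 0.0971), fatty acid synthesis (0.0923 and 0.155) and the G2/M list (0.282 and 0.118) were not called. The G2/M list was also not called without replicate 3 of the wild type or of the mutant without ethanol (0.125 and 0.0618). Fatty acid synthesis was not called without replicates 1 or 2 of the wild type or 1 of the mutant without ethanol, or 2 of the wild type with ethanol (0.0712, 0.0727, 0.0523 and 0.108), nor without the lowest 25% of genes (0.104). Drug resistance was not called without replicates 2 or 3 of the wild type or 3 of the mutant without ethanol (0.0572, 0.0576 and 0.0618), nor without replicates 1 or 2 of the wild type or 1 or 3 of the mutant with ethanol (0.0974, 0.0657, 0.0708 and 0.146).

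The count of 66 was 448 without replicate 3 of the wild type in the ethanol medium and 42 without replicate 2 there. It was 17, 20 and 42 without replicates 1, 2 and 3 of the wild type without ethanol, 16 and 22 without replicates 2 and 3 of the mutant without ethanol, 23 without replicate 3 of the mutant with ethanol, and 3 with all 12 arrays.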

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

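The E. coli control, RNA degradation and growth tests below, and the look at phosphate genes near the brightest signals, were chosen after the results were seen. The other tests were written before. The results here stand out because the strain effect differed between the media by the interaction test, or because a signal appeared in data outside the comparisons. Among the named genes the interaction was higher in the mutant for AUS1 (0.796), YLR460C (0.759), GTT2 (0.693), AGA1 (0.670) and YCR102C (0.668) on the log2 scale. It was lower for PHO5 (-2.50), PHO84 (-2.22), PHM6 (-1.87), PHO11 (-1.80) and VTC3 (-1.11), and for the list members MCR1 (-0.525), NQM1 (-0.867), CYC1 (-0.490), QCR2 (-0.313), QCR9 (-0.258), RIP1 (-0.329) and GPP2 (-0.381). The calls of AUS1, AGA1, NQM1, QCR2, QCR9, RIP1 and GPP2 ended when some single arrays were left out, and those of the other named genes did not. By list, the median interaction was -0.538 for the phosphate regulon, -0.278 for the general stress response, -0.255 for the respiratory chain, -0.233 for osmotic response and -0.0972 for G2/M and M/G1 genes. It was 0.228 for the iron regulon, 0.160 for drug resistance and 0.0731 for fatty acid synthesis. With an estimated correlation only the phosphate list kept its call (adjusted p = 0.0226), against 0.0819 for the respiratory chain, 0.915 for fatty acid synthesis and 0.802 for the 5 others.

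Of 17 phosphate genes, 13 were higher in the mutant without ethanol, against 2 higher and 1 lower in the ethanol medium. A ceiling of the array could hide a difference with ethanol, but 8 of the 11 phosphate genes called in the interaction lay over 1 log2 unit below the brightest 1% of genes, at 13.68. For the other 3, PHO84, VTC1 and VTC4, it cannot be told. A slower or later growth stage of the mutant cultures would lower ribosome biogenesis genes by about -0.33, scaled from the wild type's medium response, and their median was 0.00754. That profile is assumed, and 20 of 30 general stress, 5 of 18 trehalose and 8 of 32 respiratory genes were higher in the mutant, though these lists had adjusted p = 0.375, 0.633 and 0.333 with an estimated correlation. Slower growth therefore stays open, as do RNA quality, which differed between these groups, and the mutant protein.

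The respiratory chain genes rose less with the ethanol medium in the mutant. If short transcripts or the signal level caused this, random lists matched on gene length and mean signal would often have so low a median. Of 10000 such lists 0 did, which gives a share of at most 1e-04, and the lowest matched median was -0.0977. Random draws leave out that the list's genes vary together (estimated correlation 0.167), so this share is too small. The middle of the matched medians was -0.0273, against -0.255 for the list. A single array could also have caused the lower rise. The median closest to 0 with 1 array left out was -0.232, and the highest camera adjusted p was 1.16e-10. Both tests argue against these explanations, the first by the small shift of the matched lists and not by the share. A strain difference stays open, as does RNA quality acting other than by length or signal, and the list's adjusted p was 0.0819 with an estimated correlation.

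The array whose title calls it an outlier was not used in the comparisons. On it MET17, of which BY4741 has no working copy, read 10.9, and the S. pombe probe sets had a median of 6.687. Their 95th percentile was 10.78, against 7.104 to 7.362 on the other 11, so their upper end rose more than their median. Less labelled yeast RNA could explain a general rise: the E. coli controls added at hybridisation read 10.95 there and at most 9.299 on the other 11. Whether it explains the uneven rise or the MET17 value was not tested. RNA of fission yeast can be neither supported nor excluded, since S. pombe ribosomal protein probe sets rose only 0.168 more than other S. pombe probe sets, with a bootstrap interval of -1.25 to 1.43. A swap within the series alone would give a high correlation with some group mean. The highest was 0.786, with the array's own labelled group, and it was 0.784 with the wild type in the ethanol medium. The lowest between any 2 other arrays was 0.943. An array so far from every group cannot show which culture it came from, so a swap together with another fault stays open. The median difference between 3' and 5' probe sets was 0.289 on this array, against up to 0.435 on the others. Its S. pombe 95th percentile of 10.78 lay above its yeast median of 9.89, and such background can shrink that difference. RNA degradation of this array can therefore be neither supported nor excluded.

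Among the 3470 probe sets with no gene named, 92 changed with the ethanol medium in the wild type, 71 higher and 21 lower. Their counts were 34 for the medium in the mutant, and 3 without and 2 with ethanol between the strains. The interaction had 0 by limma's adjusted p, with 168 below 0.05 unadjusted. Of the 1746 S. pombe probe sets used as background, 14 changed with the medium in the wild type and 3 in the mutant.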

How the results depend on the processing

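No test of this part was chosen after the results were seen. Arrays limit the results here by signal over background and by their number. With all 12 arrays, 13 genes changed between the strains without ethanol and 0 with ethanol (limma, where 638 passed before), 408 and 744 with the medium in the wild type and mutant, and 3 in the interaction. The interaction then had 13 gene lists called, and the agreements were 0.249 for the strain effect and 0.730 for the medium effect. With array weights, the array labelled an outlier weighed 0.00412, 2726 genes changed between the strains without ethanol and 486 in the interaction, and the agreements were 0.330 and 0.864. Without ethanol, replicate 2 of the mutant weighed 10.6 and replicate 2 of the wild type 6.38, against 0.53 to 2.72 for the remaining arrays. The weighted fit thus leans on these replicates. The outlier array's distance from its group shows the cause of the first set, and the cause was not tested for the rest.

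All 16 reversed directions came with all 12 arrays, none past the threshold. Between the strains with ethanol the log2 changes became 0.159 for SPS22, -0.237 for URA3, -0.177 for YDJ1, -0.00478 for HSP31, -0.0406 for YPS3, -0.0875 for GSC2, -0.0352 for GPP2, -0.0901 for GRE2, -0.0512 for ICT1, -0.177 for YOR1, -0.0804 for MEP3, -0.0998 for THI20, -0.225 for BUR6 and -0.231 for SPT8. With the medium in the mutant they became -0.0647 for NCP1 and -0.162 for TAF2.

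At an adjusted p under 0.01, by construction fewer genes passed: 369 without ethanol, 89 with ethanol and 16 in the interaction. With only the groups compared, 6 genes changed between the strains with ethanol, where fewer arrays estimate the spread. That alternative gives no interaction or agreement. An estimated correlation ended 66 of 68 list calls, against 15 with all 12 arrays. With it 1, 0, 0, 0 and 1 lists were called in the 5 comparisons, in the report's order, and with fry 25 for the medium in the mutant and 2 in the interaction. Camera with an estimated correlation asks the same question with the correlation taken from the data. It also tests with the 7 residual degrees of freedom, where the preset setting uses a number near that of the genes. These changes were not told apart. The estimated correlation ranged from -0.0178 for hypoxic genes to 0.874 for the general stress list, against the preset 0.01. Most of camera's list calls thus depend on the preset setting. The vacuolar ATPase list lost its call without ethanol at -0.00167, so a higher correlation is not the whole difference. Fry asks another question by construction.

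With 1 array left out, genes changed between the strains ranged from 454 to 974 without ethanol and from 72 to 1326 with ethanol. Genes changed with the medium ranged from 2932 to 3339 in the wild type and from 2535 to 3485 in the mutant, and the interaction from 16 to 448. Lists called in the interaction ranged from 5 to 12. The agreement of the strain effect ranged from 0.366 to 0.522 and that of the medium effect from 0.876 to 0.922. Among the 391 named results, 4301 leave-one-out values in all, 3972 kept their direction and side of the threshold, 302 lost the call, 27 gained one and 0 reversed. Of the named genes, 378 of 391 were the same with array medians aligned, 383 with a repeated quantile normalization, 384 with a variance trend and robust fitting, and 292 of 348 with only the groups compared. Without the lowest 25% of genes, 275 of the 279 left were the same. With all 12 arrays only 171 of 391 were the same, while 204 lost the call and 16 reversed.

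The replicate numbers were not taken as pairs, because 11 but not all of 15 same-numbered pairs correlated above 0.1 after group means were removed. They ranged from -0.247 to 0.709 with a median of 0.185, against -0.126 for differently numbered pairs. All 4 pairs at or below 0.1 involve the wild type without ethanol, and the 7 pairs among the other groups lay from 0.257 to 0.709. Of these groups, those compared share 2 numbers, and the groups that share 3, the mutant without and the wild type with ethanol, were not compared. In all, 6 of 11 arrays correlated best with an array of their own number. With the number as a block, the counts were 1030, 552, 3457, 3503 and 46 genes in the report's order. Of 391 named results 9 lost the call and 2 gained one. Between the strains with ethanol those of PES4 (adjusted p = 0.0533), RPS22B (0.0578), RPS18A (0.0712), YDJ1 (0.0519), CCC2 (0.0740) and TOA1 (0.0533) ended, as did those of QCR2, QCR9 and RIP1 (0.0580, 0.0582 and 0.0686) and of the drug resistance list (0.0721) in the interaction. The log2 values were -0.646 for PES4, -0.312, -0.259 and -0.319 for QCR2, QCR9 and RIP1, and a median of 0.159 for the list, against -0.677, -0.313, -0.258, -0.329 and 0.160 without the block. HXT2 and SIS1 between the strains with ethanol gained calls (0.0347 and 0.0415).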

Other observations

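No test in this part was chosen after the results were seen, but BUR6, MOT1, NCB2, HXT5 and LEU2 were singled out after their values were seen. Of the genes that regulate the TATA-binding protein, some differed between the strains although the list of 34 that holds them was not called in either medium (camera adjusted p = 0.363 and 0.181). BUR6, a subunit of the negative cofactor NC2, was 1.63-fold higher in the mutant without ethanol and higher by 0.39 on the log2 scale with ethanol. MOT1, which removes the protein from DNA, was higher by 0.53 and 0.63. Both lost their calls with ethanol when only the groups compared were used (adjusted p = 0.134 for BUR6 and 0.128 for MOT1). NCB2, the other subunit of NC2, was higher by 0.20 without ethanol (adjusted p = 0.0128), a call that ended without replicate 2 of the wild type (adjusted p = 0.0548). In each medium 3 genes of the list rose and 1 fell (3 and 0, and 4 and 2, adjusted over the list alone).

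HXT5 was higher in the mutant in both media, by 0.99 and 1.13, while the hexose transport list of 17 was not called (camera adjusted p = 0.0947 and 0.690). LEU2, of which BY4741 has no working copy, read 7.99 and 8.07 in the wild type and the mutant without ethanol and 9.65 and 10.21 with ethanol. What its probe set measures in these cells was not tested.

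A hypothesis was that the mutant without ethanol partly resembles wild type cells in the ethanol medium. Both effects were higher for 301 genes, against 142.9 for independent lists, and both lower for 173, against 127.7, with 58 and 116 in opposite directions. Both effects share the wild type arrays without ethanol, which those expected counts leave out and which alone produce a positive covariance. The Pearson correlation was 0.366, below the average of 0.460 for simulated unchanged groups. The covariance across genes was 0.0301, and simulations of unchanged groups against the same controls gave 0.00337 on average and 0.0375 at most, with 1 of 1000 as large. The difference from the simulated average was 0.0267. By the bound set beforehand, the highest simulated value, the shared controls were not excluded, and part of the excess may come from them. The controls were not split, since 3 arrays do not leave 2 for each effect.

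Splitting the 6 arrays of a comparison in every other way tests how often chance gives as many changed genes. For the strains without ethanol, 1 of 10 splits gave 890 or more, the real split itself, and the highest other gave 0. For the medium in the wild type, 1 of 10 gave 3312 or more, again the real split, and the highest other gave 1. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes arrays of both groups, so any difference between the groups, whatever its origin, adds to the spread. The low counts of the other splits therefore do not tell a strain or medium effect from RNA quality.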
